A study of Sus scrofa with 39 samples.

How the data were processed

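Whole-blood RNA from 39 preterm, formula-fed piglets was sequenced: 19 without necrotizing enterocolitis (CON) and 20 with it (NEC), a disease in which the wall of the immature gut becomes inflamed and dies. The labels give each NEC piglet a severity (11 mild, 9 severe), and give every piglet a sex and 1 of 3 batches; the diagnosis was made at necropsy on day 5. The day on which blood was drawn is not given in the sources used here. Per the labels' protocols, RNA was extracted with a MagMax blood kit, made into mRNA-seq libraries and sequenced as paired-end reads on an Illumina sequencer. The deposited values are raw read counts per Ensembl pig gene, 1 file per piglet and no pooling recorded. Per the submitters' processing notes, the authors used Trim Galore, TopHat, HTSeq and DESeq2 and the build Sscrofa11.1; versions, annotation release, counting mode and strand setting are not given in the sources used here.

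Each file holds 25880 genes and 5 closing lines that name no gene. Those lines stayed out of library sizes and tests. Relative to the counts on genes and closing lines together, reads outside features made up a mean of 2.2%, ambiguous reads 7.48% and reads aligned to several places 30.5%, with a range of 16.4 to 51.9% for the last; the other 2 lines were 0 in every file. Symbols came from the table that pairs Ensembl pig IDs with names, which named 14857 of the genes; coordinates came from a RefSeq gene table of Sscrofa11.1. Genes without a symbol were tested under their ID. Counts on near-identical copies, such as globin and histocompatibility genes, are uncertain, because reads aligned to several places were not assigned to any gene, and strand use is unknown for overlapping genes. Counts on genes ranged from 12.82 to 28.96 M (mega) per library. No 2 libraries of a group agreed within sampling noise: the lowest chi-square per degree of freedom was 9.61.

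The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) with robust dispersions, TMM scaling and Benjamini-Hochberg adjustment over all tested genes, called at an FDR of 0.05. The filter filterByExpr, run on the 3 groups with its minimum count of 10, kept 10731 genes, 9303 of them with a symbol. All 39 piglets entered every fit. NEC against CON was fitted with batch and sex as terms. Mild against CON, severe against CON and severe against mild were contrasts of 1 fit with a severity factor of 3 levels, batch and sex; the within-batch differences and the interactions of NEC with batch and with sex came from fits with those terms. An error after a log2 fold change is a standard error derived from that fit's test: the size of the change divided by the square root of F. The labels name separate piglets, so each library was 1 replicate.

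The 29 gene lists, covering blood cell types, other cells, pathways and RNA quality, were tested with camera (limma 3.58.1) on voom values with its preset correlation of 0.01, and again with the correlation estimated for each list and with fry. A list needed at least 3 tested genes, which 28 had. The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined, except for tests of the library composition of mild and severe piglets apart and those that the closing section names as chosen later. That rule took, of genes with a symbol, an FDR under 0.05 and a mean of at least 5 CPM (counts scaled to library size), the 12 higher and 12 lower with the largest change for NEC against CON, which also had to keep their sign in each batch, and the 6 higher and 6 lower for each severity comparison. Where nothing passed, the 3 genes with the smallest p were named as values. Up to 4 members with the smallest p were named per list, a few of which are not reported here, and the 5 genes with the smallest p per interaction and sex test, Y-linked genes apart. AOAH, ARG2, FKBP5 and PAK2 were fixed by name in every comparison; they were chosen from knowledge of the study on these samples, so their values are not independent evidence.

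Other results came from permutation tests, 2-sided: exact ones in which a score of 50 higher minus 50 lower genes, taken from 2 batches, was compared between NEC and CON in the batch left out, and tests of library composition with labels exchanged within batches (100000 resamples, or every arrangement for the severe piglets). A correlation of the mild and severe fold changes was set beside simulated unchanged groups against the same controls and beside split controls. Labels of the piglets were also exchanged within batches 100 times per fitted comparison.

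Alternatives were DESeq2 1.42.0 as a test, DESeq2's size factors in edgeR, limma voom with sample weights, no low-count filter, a filter of at least 1 CPM in at least 20 libraries, no sex term, no batch and sex terms, the number in the piglet's title in place of batch, surrogate variables from sva 3.50.0, and the removal of globin genes. Libraries were left out as well: the 4 control libraries of batch 3 whose label series (BKDL) differs from the rest of that batch, batch 2, and each piglet in turn. Fits without 3 doubted libraries and without the 2 most abundant genes were added after seeing the data. The closing section gives their effect.

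The gene and list tests were first tested on simulated counts for the same 10731 genes, with 50 genes changed at each of log2 0.5, 1, 1.5 and 2. For severe against CON, edgeR called 12, 42, 86 and 84% of the changed genes at these sizes, with 6 false calls. For NEC against CON it called 28, 66, 92 and 96%, with 11 false calls; for mild against CON 12, 46, 84 and 84%, with 4 false calls; and for severe against mild 2, 40, 82 and 84%, with 6 false calls. With no gene changed it made 0, 0, 1 and 0 calls for NEC, mild and severe against CON and severe against mild. A simulated rise of the monocyte list by log2 0.5 was found by camera, and 0 of 27 other lists were called; simulated genes vary independently, which real lists do not.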

Results

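Blood transcriptomes were measured in 19 control piglets (CON), 11 piglets with mild and 9 with severe necrotizing enterocolitis (NEC); 19 of the 39 piglets were labelled female and 20 male. Batch 1 held 7 CON, 4 mild and 3 severe piglets, batch 2 held 5 CON and 4 severe piglets and no mild one, and batch 3 held 7 CON, 7 mild and 2 severe piglets. Counts on genes averaged 17.6 M (mega) in CON libraries (SD 2.35, n = 19), 21.5 M in mild (SD 4.24, n = 11) and 19.5 M in severe (SD 4.51, n = 9). Red cell RNA took most of them: HBB, the beta-globin gene, held a mean of 56.0% of counts (23.4 to 67.8%), and a second gene without a symbol (ENSSSCG00000007978) held 22.6%. This left 1.51 to 12.6 M counts per library for all other genes. The 4 BKDL controls of batch 3, a separate library series in the labels, had 46.6% of reads aligned to several places (SD 10.3), against 29.1% (SD 11.7) in its other 3 controls. CON replicate 16, a BKDL library, stood apart, with 24.1% of its counts on globin genes and a TMM factor of 4.09, against 0.308 for the lowest library.

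**Figure D1:**
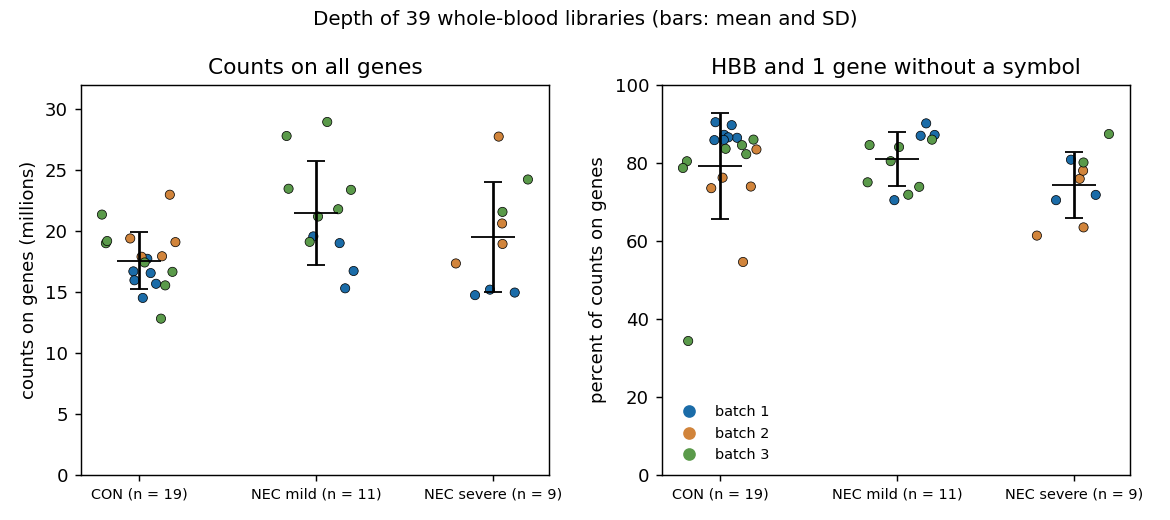
Counts on genes in M (left) and the percent of them on HBB and the gene without a symbol (right) for each of 39 libraries, coloured by batch, with the mean and SD of each group. CON replicate 16 is the lowest point on the right, at 34.3%.

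The share of counts on globin genes with a symbol, which leaves out the abundant gene without one, was 56.5% in CON (SD 9.82, n = 19) and 56.0% in NEC (SD 7.05, n = 20). The within-batch difference was -0.82 percentage points (permutation p = 0.781). Genes encoded by mitochondrial DNA held 0.377% of counts in CON (SD 0.195) and 0.448% in NEC (SD 0.194; permutation p = 0.131, adjusted p = 0.262). The 10 most abundant genes held 82.8% in CON (SD 12.9) and 81.8% in NEC (SD 7.95; permutation p = 0.714). NEC libraries had more counts on genes, by 2.88 M within batches (permutation p = 0.00321, adjusted p = 0.0128 over 4 measures). Without the 4 BKDL controls the difference was 2.01 M (permutation adjusted p = 0.0779), that of the globin share -3.34 points (permutation p = 0.112) and that of the 10 most abundant genes -4.39 points (permutation p = 0.0584, adjusted p = 0.0779). That of the mitochondrial share was then 0.0982 points (permutation p = 0.0492, adjusted p = 0.0779). In tests added after seeing the data, the mild piglets alone were 3.6 M above CON (permutation adjusted p = 0.00316) and the severe piglets 1.52 M above (exact permutation adjusted p = 0.592).

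The comparison of all NEC with CON piglets asks whether blood carries markers of the disease. The genes with the smallest p were TUBA1B, an alpha-tubulin, at a log2 fold change of -0.58 ± 0.12 (60.9 CPM ± 19.1 SD in 19 CON, 40.5 ± 5.65 in 20 NEC), DOK2 and SUDS3. DOK2, a docking protein of blood cell receptors, read -0.55 ± 0.12, and SUDS3, part of a histone deacetylase complex, 0.34 ± 0.07. None passed, at adjusted p = 0.116 for each. TUBA1B read -0.72, -0.39 and -0.56 in batches 1, 2 and 3. Of the 4 genes fixed by name, chosen from knowledge of the study on these samples and so not independent evidence, AOAH, which deacylates bacterial lipopolysaccharide, read 0.66 ± 0.18 (adjusted p = 0.152). The arginase ARG2 read 0.70 ± 0.25 (adjusted p = 0.209), the glucocorticoid receptor co-chaperone FKBP5 0.52 ± 0.19 (adjusted p = 0.211) and the kinase PAK2 0.39 ± 0.12 (adjusted p = 0.172). edgeR called 0 of 10731 genes, DESeq2 55 and limma 127, and 1549 genes had an unadjusted p under 0.05 where chance gives 537 on average. Exchanges of labels reached that count in 2 of 100 splits, the real one included, with 2749 as the highest other.

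Among gene lists, T cell genes were lower as a group in NEC: 29 of 31 tested members read below CON, with CD6 at -0.50 ± 0.16, CD247 at -0.51 ± 0.16, CD5 at -0.53 ± 0.17 and LCK at -0.42 ± 0.14. Camera gave the list an adjusted p of 2.76e-07, and adjusted p = 0.761 with an estimated correlation; 0 members passed over all genes and 4 when adjusted over the list alone. The mean log2 CPM of the T cell list in batch 1 was 2.639 in CON, 2.854 in mild and 2.448 in severe piglets, so mild piglets were not lower there. It was 3.109 in CON and 2.453 in severe piglets in batch 2. In batch 3 it was 2.725 in CON, 2.415 in mild and 1.923 in severe piglets. Platelet genes were lower in 24 of 29 members, with PTGS1, the cyclooxygenase of platelets, at -0.78 ± 0.23, CLU at -0.76 ± 0.22, TUBB1 at -0.59 ± 0.18 and GP9 at -0.72 ± 0.24. Camera gave an adjusted p of 8.34e-05 (adjusted p = 0.761 with an estimated correlation), and 0 members passed over all genes and 12 adjusted over the list alone. B cell genes were also called lower (15 of 23 members below CON), and the cytokine and receptor list (31 of 40 above CON, JAK2 at 0.46 ± 0.16) and the mitochondrially encoded genes (12 of 13 above CON) were called higher. For these 3 lists, too, adjusted p = 0.761 with an estimated correlation. The mean log2 CPM of the mitochondrially encoded genes was 5.13 to 5.78 in the 4 BKDL controls of batch 3, below its other 3 controls (6.18 to 6.74). Exchanging the piglets' labels within batches gave at least as many called lists in 89 of 100 splits, and in 79, 14 and 9 of 100 for mild against CON, severe against CON and severe against mild. Chance is therefore not excluded for the number of lists called in any of these comparisons.

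Mild NEC against CON asks for a difference at the weaker grade of disease. The genes with the smallest p were LENG9 at -1.03 ± 0.24 (1.36 CPM ± 0.56 SD in 19 CON, 0.718 ± 0.349 in 11 mild), TUBA1B at -0.63 ± 0.15, and GSTO2, a glutathione transferase, at 1.21 ± 0.30, each at adjusted p = 0.498. AOAH read 0.49 ± 0.22, ARG2 0.46 ± 0.31, PAK2 0.29 ± 0.15 and FKBP5 0.0018 ± 0.21. edgeR called 0 genes, limma 0 and DESeq2 20, with 841 genes at an unadjusted p under 0.05, a count that 12 of 100 exchanges of labels reached. Platelet genes were the list with the smallest p: 26 of 29 read below CON, with ESAM at -0.78 ± 0.24, PTGS1 at -0.87 ± 0.29, TREML1 at -0.77 ± 0.27 and GP9 at -0.85 ± 0.31 (camera adjusted p = 5.47e-07; adjusted p = 0.546 with an estimated correlation). B cell genes went the other way, with 20 of 23 above CON, FCRL1 at 0.81 ± 0.25, EBF1 at 1.06 ± 0.36 and MS4A1, which encodes CD20, at 0.69 ± 0.24. Camera gave an adjusted p of 0.000221 (adjusted p = 0.602 with an estimated correlation), and 3 passed adjusted over the list alone. All 13 mitochondrially encoded genes read above CON, ND4L at 1.48 ± 0.43 (camera adjusted p = 7.16e-07; adjusted p = 0.546 with an estimated correlation; 2 adjusted over the list alone). Erythroid genes were called higher (36 of 41 above CON), and monocyte genes (15 of 18 below) and adhesion and migration genes (26 of 35 below) lower, each with adjusted p = 0.871 with an estimated correlation. The batches differed: the mean log2 CPM of mild and CON piglets was 2.32 and 1.78 in batch 1 and 1.63 and 1.58 in batch 3 for B cell genes. For monocyte genes it was 2.59 and 3.28 in batch 1 but 3.64 and 3.58 in batch 3, and for adhesion and migration genes 4.99 and 5.30 but 5.24 and 5.19. For mitochondrially encoded genes it was 6.531 and 6.408 in batch 1 and 6.955 and 5.945 in batch 3. The 4 BKDL controls of batch 3 read 5.13 to 5.78 for these genes, and its other 3 controls 6.18 to 6.74. NEC_Mild replicate 1 stood apart, at 2.83 for B cell, 1.46 for platelet and 1.70 for monocyte genes, and NEC_Mild replicate 10 read 2.07 for monocyte genes.

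Severe NEC against CON gave the clearest gene differences. The scavenger receptor CD163 of monocytes and macrophages (ENSSSCG00000033146; Sscrofa11.1 chromosome 5, 63300200 to 63334497) rose by log2 1.68 ± 0.42, from 31.6 CPM ± 36.3 SD in 19 CON to 96.0 ± 62.1 in 9 severe piglets (edgeR FDR 0.0302). The activin receptor ACVR1B rose by 1.40 ± 0.38, NIBAN1 by 1.28 ± 0.32, the death receptor TNFRSF21 by 1.26 ± 0.28, the proteoglycan VCAN by 1.21 ± 0.28 and GAS7 by 1.11 ± 0.30. ID3, which encodes a helix-loop-helix inhibitor of lymphocyte differentiation factors (ENSSSCG00000039514; Sscrofa11.1 chromosome 6, 81422541 to 81424169), had the smallest FDR of any gene at 0.00309: it fell by 1.60 on the log2 scale (SE 0.26), from 6.61 CPM ± 2.43 to 2.37 ± 1.25. ARHGEF16 changed by -1.01 ± 0.23, the transcription factor SOX13 by -1.003 ± 0.26, the B cell and dendritic cell factor SPIB by -0.92 ± 0.23, the class II chain HLA-DRA by -0.91 ± 0.24 and the B lymphoid kinase BLK by -0.91 ± 0.24.

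Of the genes fixed by name, AOAH (0.84 ± 0.22, edgeR FDR 0.0365) and FKBP5 (0.94 ± 0.20, FDR 0.0167) rose, while ARG2 at 0.92 ± 0.30 (FDR 0.0848) and PAK2 at 0.50 ± 0.15 (FDR 0.0667) did not pass. edgeR called 224 genes, 115 higher and 109 lower, with a median absolute log2 fold change of 0.88; DESeq2 called 542 and limma 1701. In their pooled direction these 224 genes had a median of 0.81 in batch 1 (3 severe piglets), 0.90 in batch 2 (4) and 0.79 in batch 3 (2). The pooled fit that chose them holds the same batches. For the 224 genes with the smallest p in the other 2 batches, a choice made after the values were seen, the median was 0.29 in batch 1, 0.32 in batch 2 and 0.23 in batch 3, against 0.98, 1.10 and 1.02 in the batches that chose them. Calls within single batches were uneven, with 16 genes in batch 1, 1 in batch 2 and 270 (87 higher, 183 lower) in batch 3. The count leaned on single libraries: without NEC_Severe replicate 2, a library labelled male with 0 counts of KDM5D and 1 of EIF1AY whose sex label or identity is in doubt, 12 genes were called, and without NEC_Severe replicate 9, which detected the fewest genes, 721. Without batch 2 it was 12 and with surrogate variables added 0 (818 genes at an unadjusted p under 0.05).

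**Figure D2:**
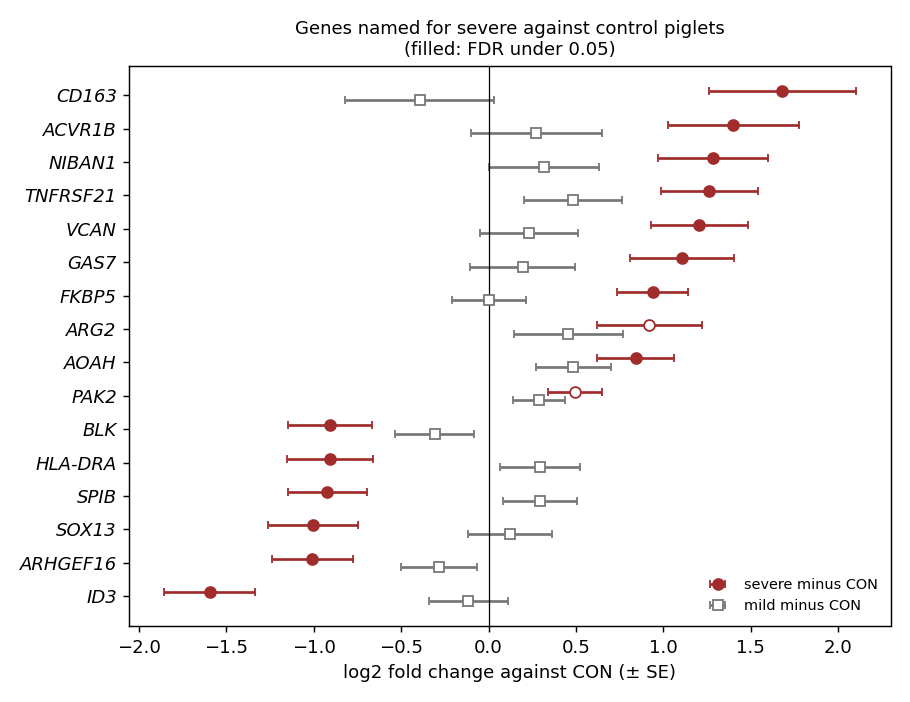
Log2 fold change against CON, with its standard error, for 16 genes named in the comparison of severe piglets, in 9 severe (red circles) and 11 mild piglets (grey squares) against 19 CON; filled symbols have an edgeR FDR under 0.05. The 14 filled red circles run from -1.60 for ID3 to 1.68 for CD163, and none of the grey squares is filled.

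The monocyte and neutrophil lists were called higher in severe piglets by camera with its preset correlation. In the monocyte list 17 of 18 members read above CON and 4 rose: VCAN, CD163, the growth factor receptor CSF1R by 0.82 ± 0.22 and the ficolin FCN2 by 1.26 ± 0.35. Adjusted over the list alone 9 passed (camera adjusted p = 2.52e-07; adjusted p = 0.274 with an estimated correlation; fry adjusted p = 0.0211). Neutrophil granule genes were above CON in 15 of 17 members and 1 rose, the protease inhibitor SLPI by 1.57 ± 0.38. Mature neutrophil genes were above CON in 14 of 16, with KCNJ15 at 1.65 ± 0.53 and none passing (for the 2 lists, adjusted p = 0.274 and 0.358 with an estimated correlation). In the list for Toll-like receptor and lipopolysaccharide signalling, TNIP3, an inhibitor of NF-kB, rose by 1.35 ± 0.33, TLR8 by 1.04 ± 0.26 and AOAH as above. In it 36 of 47 members read higher and 7 passed adjusted over the list alone (camera adjusted p = 0.000246; adjusted p = 0.274 with an estimated correlation). Acute phase and complement genes read higher in 10 of 16 members and lower in 6, and 5 higher and 1 lower passed adjusted over the list alone. They included rises of VSIG4 by 1.30 ± 0.31, FCN2 and the receptor C5AR2 by 1.06 ± 0.30, with ITGAM at 0.92 ± 0.27 not passing (adjusted p = 0.274 with an estimated correlation).

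Glucocorticoid response genes read higher in 20 of 28 members: FKBP5, IRS2 by 1.18 ± 0.27, CD163 and the annexin ANXA1 by 0.95 ± 0.25 rose (camera adjusted p = 0.000591; adjusted p = 0.274 with an estimated correlation). Of 40 cytokine and receptor genes 31 read higher and none passed over all genes, with CSF2RB at 0.79 ± 0.24, JAK2 at 0.64 ± 0.20 and STAT3 at 0.49 ± 0.16. Of the 40 genes 8 higher and 1 lower passed adjusted over the list alone (adjusted p = 0.274 with an estimated correlation). Inflammasome genes read higher in 14 of 17, NLRP3 at 0.78 ± 0.25, again with none passing (adjusted p = 0.274 with an estimated correlation; fry adjusted p = 0.0308). The adhesion and migration list, in which the integrin ITGAL rose by 0.54 ± 0.15, and the immediate early list were called higher too (adjusted p = 0.454 and 0.368 with an estimated correlation).

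The B and T cell lists were called lower by camera with its preset correlation, while natural killer and cytotoxic genes read above CON in 13 of 20 members and were not called (camera adjusted p = 0.808). All 23 tested B cell genes read below CON and 5 fell. Among these the chemokine receptor CXCR5 changed by -1.14 ± 0.26, SPIB and BLK as above, and the antigen receptor chain CD79A by -0.66 ± 0.17. Of them 12 passed adjusted over the list alone (camera adjusted p = 5.18e-11; adjusted p = 0.163 with an estimated correlation; fry adjusted p = 0.000409). T cell genes read lower in 29 of 31 members, and LCK, the kinase of the T cell receptor (-0.63 ± 0.18), and GATA3 (-0.74 ± 0.21) fell. Adjusted over the list alone 15 passed (camera adjusted p = 1.56e-10; adjusted p = 0.274 with an estimated correlation; fry adjusted p = 0.0211). Class II genes read lower in 11 of 16, with HLA-DRA passing and CD74 at -0.89 ± 0.26 not (adjusted p = 0.389 with an estimated correlation). Reads of these near-identical genes can be lost or shared, so single values are uncertain. Platelet genes (25 of 29 lower, CLU at -0.93 ± 0.30) and ribosomal protein genes (37 of 43 lower) were called lower, at adjusted p = 0.63 and 0.858 with an estimated correlation. The batches differed: in batch 3, with 2 severe piglets, the mean log2 CPM of ribosomal protein genes was 8.144 in severe and 7.392 in CON. For class II genes it was 3.122 and 3.11 there. Both lists were lower in severe piglets in batches 1 and 2. Interferon-stimulated genes were not called (camera adjusted p = 0.356), with 32 of 49 below CON.

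**Figure D3:**
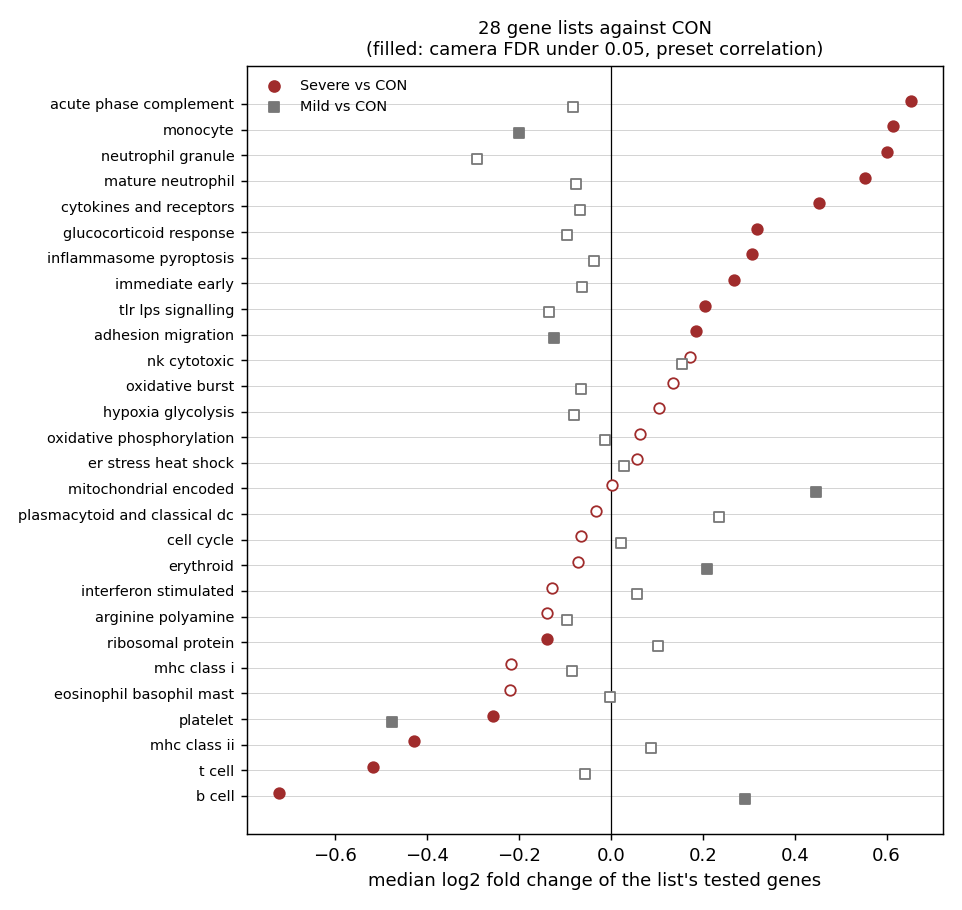
Median log2 fold change against CON over the tested genes of 28 lists, for severe (red circles) and mild piglets (grey squares); filled symbols have a camera FDR under 0.05 with the preset correlation, and none of them keeps it with an estimated correlation. The severe medians run from -0.72 for B cell genes to 0.65 for acute phase and complement genes. The sign of the median depends on the scaling for mitochondrially encoded genes in severe piglets and for eosinophil and oxidative phosphorylation genes in mild ones.

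Severe against mild NEC tests the difference between the grades itself. B cell genes set them apart: all 23 read lower in severe piglets and 5 fell, among them FCRL1 (-1.65 ± 0.32), MS4A1 (-1.57 ± 0.31) and CD79A (-1.09 ± 0.20). Of the 23 genes 18 passed adjusted over the list alone. This list alone kept its call with an estimated correlation (adjusted p = 0.00863). ID3 fell by 1.48 on the log2 scale (SE 0.30), SPIB by 1.22 (SE 0.27) and VAMP2, a vesicle fusion protein, by 0.67 (SE 0.14). The mean log2 CPM of the B cell list was 1.62 ± 0.27 (SD, n = 19) in CON, 1.88 ± 0.58 (n = 11) in mild and 0.89 ± 0.33 (n = 9) in severe piglets. All 18 monocyte genes read higher, with CD163 at 2.08 ± 0.53 and CSF1R at 1.03 ± 0.27, and none passed over all genes. Adjusted over the list alone 8 passed (camera adjusted p = 2.54e-12; adjusted p = 0.0692 with an estimated correlation; fry adjusted p = 0.00617). Camera called 19 lists, 12 higher and 7 lower, among them the neutrophil granule list (16 of 17 higher, adjusted p = 0.162 with an estimated correlation) and the 13 mitochondrially encoded genes, all lower (adjusted p = 0.258 with an estimated correlation). The mean log2 CPM of these 13 genes in severe and mild piglets was 5.594 and 6.531 in batch 1 but 6.982 and 6.955 in batch 3.

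edgeR called 12 genes between the grades, 11 of them lower in severe piglets; DESeq2 called 103 and limma 818. The only rise was ATP9A, by 1.40 on the log2 scale, and others that fell included VAV2, CLEC17A, RAB28 and a gene without a symbol. These 5, too low in abundance for the naming rule or without a name, were singled out after their values were seen. FKBP5 read 0.94 ± 0.25 (FDR 0.095), ARG2 0.46 ± 0.38, AOAH 0.36 ± 0.27 and PAK2 0.21 ± 0.19. Without batch 2, which has no mild piglet, edgeR called 0 genes (1474 at an unadjusted p under 0.05), and leaving out 1 piglet gave between 5 (NEC_Severe replicate 8) and 104 (NEC_Mild replicate 7).

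**Figure D4:**
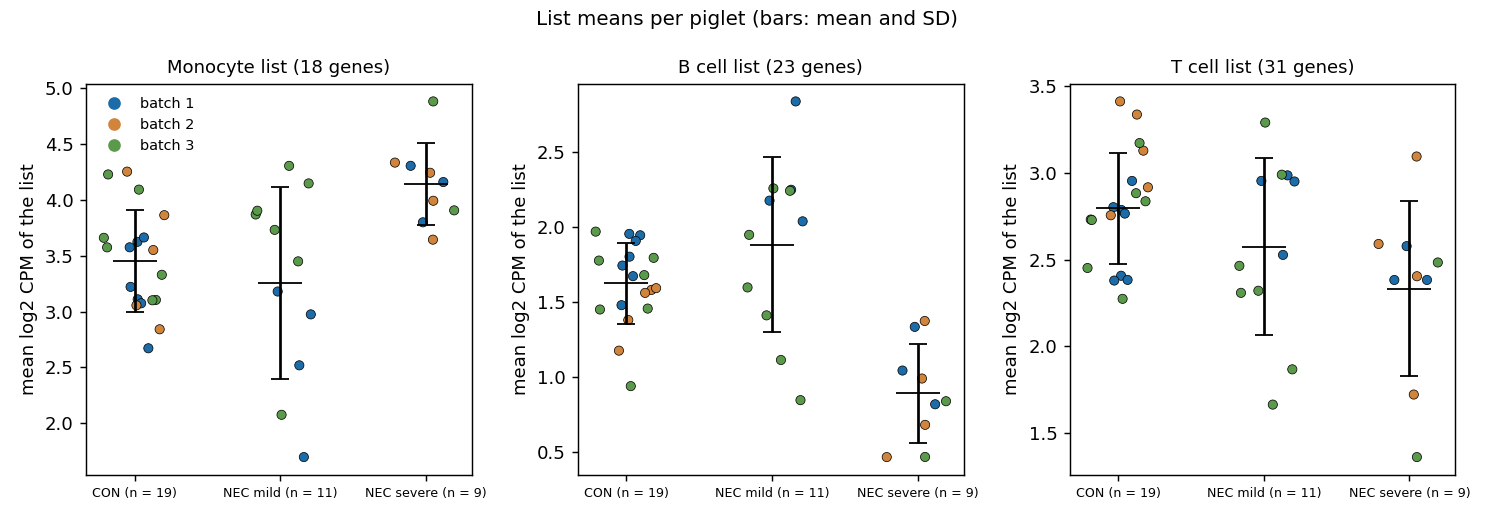
Mean log2 CPM of the monocyte, B cell and T cell lists in each of 39 piglets, coloured by batch, with the mean and SD of each group. Severe piglets average 0.89 for B cell genes against 1.62 in CON, and 4.14 for monocyte genes against 3.45.

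The 3 batches ask whether an NEC difference repeats in separate sets of piglets. Their NEC piglets differ in grade: 4 mild and 3 severe in batch 1, 4 severe in batch 2, and 7 mild and 2 severe in batch 3. A difference between batches therefore cannot be told apart from a difference between grades. In batch 3 edgeR called 15 genes, 14 of them higher in NEC, led among named genes by GSTO2 (1.89 ± 0.33), the splicing factor BUD31 (2.32 ± 0.44), CTR9 of the polymerase-associated PAF1 complex (3.69 ± 0.71) and HEPACAM, a cell adhesion gene of glia and liver (4.82 ± 0.97). PLCB3 fell by 0.91 (SE 0.20). GSTO2 had a median of 1.77 CPM in the 4 BKDL controls, 1.98 in the other 3 controls and 5.93 in NEC. CTR9 had a median of 34.9 CPM in NEC, with 1 library at 1090, and 9.49 in controls (6.12 to 19.3). Among controls it was 7.28 in the 4 BKDL libraries and 15.9 in the other 3. BUD31 had a median of 1.32 CPM in NEC, 0.206 in the BKDL controls and 0.37 in the other 3. HEPACAM had a median of 19.7 CPM in the 4 BKDL controls of that batch, 1330 in its other 3 controls and 3010 in its 9 NEC piglets. In batch 1 it stood at 0.191 in CON and 0 in NEC, and in batch 2 at 2370 in CON and 793 in NEC. CTR9 (46.1 CPM in CON, 32.9 in NEC) and BUD31 (1.17 and 0.934) were also lower in NEC by their medians in batch 2. GSTO2 was higher in NEC by its median in batch 2 (1.14 CPM in CON, 2.82 in NEC) but not in batch 1 (1.72 and 1.38). Without the BKDL controls, or with batch 3 fitted alone, edgeR called 0 genes (387 and 715 at an unadjusted p under 0.05). In batches 1 and 2 edgeR called 0 genes, with 756 and 1114 at an unadjusted p under 0.05. SERPINF2 had the smallest p in batch 1 (-1.70 ± 0.33, adjusted p = 0.083) and PLIN2, which coats lipid droplets, in batch 2 (2.04 ± 0.40, adjusted p = 0.0965). The interaction of NEC with batch gave 0 calls in edgeR (715 at an unadjusted p under 0.05) and 4 in DESeq2, with HEPACAM, ENSA and CTR9 smallest in p at adjusted p = 0.256, 0.275 and 0.28.

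A score of 50 higher minus 50 lower genes chosen in 2 batches differed between NEC and CON in the third by 0.07 in batch 1 (7 and 7 piglets, exact permutation p = 0.791), 0.29 in batch 2 (4 and 5, exact p = 0.397) and 0.28 in batch 3 (9 and 7, exact p = 0.435). After adjustment over the 3 batches the exact p values were 0.791, 0.652 and 0.652. The batches mix mild and severe piglets in unlike shares, and batch 2 has only severe ones, so the score also crosses grades. With these 50 and 50 genes the difference was positive in all 3 and within the spread between piglets in each, and with 20 and 20 genes it was -0.18 in batch 2. With 100 and 100 genes it was 0.46 in batch 2, and without the BKDL controls it was 0.35, 0.63 and 0.64 in the 3 batches (exact adjusted p = 0.286 for each).

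Mild and severe fold changes against the same controls correlated over genes, which are not independent replicates, with r = 0.282. Simulated unchanged groups against these controls gave a median r of 0.269 (0.24 to 0.299 in 20 runs), and 10 splits of the controls into separate sets gave a median of 0.089 (-0.0731 to 0.201). The covariance was 0.041, against a simulated median of 0.0232, a difference of 0.0178. The simulated genes vary independently, which real genes do not, so the simulated ranges do not show how far unchanged real groups can stray. The difference is therefore no evidence of a change shared by mild and severe piglets. Of the 224 genes called in severe piglets 176 had the same sign in mild ones, where their median in the severe direction was 0.17. Over all 10731 genes 58.8% had the same sign, and the 224 were chosen in 1 of these comparisons with shared controls, so their 176 has no value for unchanged groups beside it.

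Male against female piglets checks the labels. The Y-linked demethylase KDM5D and translation factor EIF1AY rose by log2 6.57 and 8.58, and the other 11 of 13 genes called carried no symbol, 3 of them lower in males. Among genes with a symbol and apart from Y-linked ones, PODXL2 (0.92 ± 0.21, adjusted p = 0.0657), ICAM4 (0.88 ± 0.20, adjusted p = 0.0674) and the X-linked KDM6A (-0.86 ± 0.21, adjusted p = 0.0822) had the smallest p and did not pass. NEC_Severe replicate 2, labelled male, had 0 counts of KDM5D and 1 of EIF1AY, where the other 19 libraries labelled male had 6 to 129 and 8 to 284. Its sex label or its identity is therefore in doubt. The interaction of NEC with sex gave 0 calls in edgeR (153 genes at an unadjusted p under 0.05) and 9 in DESeq2. STK35 (0.89 ± 0.22), EMC4 (-2.16 ± 0.67) and KRTCAP2 (-1.91 ± 0.64) had the smallest p, each at an adjusted p of 1.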

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

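The exchanges of labels for gene lists, for single batches, for sex and for counts at an unadjusted p, and the tests of the BKDL controls in batch 3 and of genes chosen in 2 of the 3 batches, were chosen only after the result was seen.

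In the 9 severe piglets 5 of 59 measures had a lowest or highest piglet far from the nearest other one by Dixon's test, which chance gives in about 1 of 20. NEC_Severe replicate 9 had 4 of the 5. It detected 10674 genes (nearest piglet 12581), and its PAK2 stood at log2 3.22 CPM (nearest 4.38). Its SPIB, a B cell and dendritic cell factor, was highest at log2 3.61 CPM (nearest 2.40), and so was its mean of MHC class I genes at log2 4.27 CPM (nearest 3.59). LENG9 was lowest in NEC_Severe replicate 4, at log2 -1.30 CPM (nearest -0.24).

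Severe piglets had 115 genes higher and 109 lower than CON, and with all 39 piglets chance can be excluded for this count of 224, since 1 of 100 splits, the real one, reached it and the highest other gave 27; without NEC_Severe replicate 2, or without batch 2, the count was 12, below that 27. The tables argue against the share of HBB and the abundant gene without a symbol as the whole source. That share is a stand-in for red cell RNA in which the identity of that gene is open. With it as a covariate the median change was 99.7% of its size (238 genes called, 213 of them among the 224). The 2 genes of that share were picked by their abundance in these counts, so this covariate was chosen after the counts were seen. Without the 4 BKDL controls the median change was 97.6% of its size, from 0.88 (quartiles 0.68 and 1.12) to 0.86 (0.65 and 1.09), though with 15 controls 70 genes were called. This median cannot decide on the BKDL controls. It stayed at 96.6% without the whole of batch 2, where only 4 of the 224 genes were called. With a score of neutrophil minus lymphocyte genes as a covariate (0.94 ± 0.90 SD in CON, 0.86 ± 1.69 in mild, 2.34 ± 0.95 in severe piglets) the median fell to 67.7%, at 0.60 (0.45 and 0.81), all 224 signs stayed, and as the folds shrank 13 genes were called, 7 of them among the 224. The score itself has its highest mean in the severe group. Its lists hold some of the 224 genes, among them SPIB, BLK and LCK, so part of the shrinkage was built in. It also leaves out the monocyte list. A shift from lymphocytes to neutrophils may therefore account for part of the pattern and cannot be told apart from change within cells for these genes. Batch stays open, since genes chosen in 2 batches had as little as 22.3% of their median change in the third, which the choice by p also lowers, and so does a biological difference between severe disease and CON.

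In batch 3, 15 genes differed between NEC and CON, 14 of them higher in NEC, and 2 of 100 splits of its piglets, the real one included, gave as many. Chance is not excluded by this, because the test was chosen after the result was seen and not adjusted over the many split tests. It also covers only the fit of all batches. With batch 3 fitted alone edgeR called 0 genes. The highest other split gave 62 genes, several times the real count. It put all 4 BKDL controls on the NEC side and kept 3 of 9 NEC piglets there, but another split with these same numbers gave 0 genes. The place of the BKDL controls alone therefore does not account for the 62 genes, which were not tested against that library series. Without these controls edgeR called 0 of the 15 genes and 0 overall (387 at an unadjusted p under 0.05), and their median change fell from 3.69 (quartiles 2.85 and 4.84) to 2.31 (1.98 and 3.08), 62.5% of its size, with all 15 signs kept. The calls ended as the folds shrank and the controls went from 7 to 3. The series may account for part of these folds, though not evenly. Median CPM in BKDL and other controls was 19.7 and 1330 for HEPACAM, 7.28 and 15.9 for CTR9, and 0.206 and 0.37 for BUD31. For GSTO2 it was 1.77 and 1.98. With only 3 other controls the series cannot be told apart from NEC for the 15 genes as a set.

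For severe against mild NEC, 4 of 100 splits, the real one included, reached the 12 genes called. This met the mark fixed beforehand for excluding chance, for the count with all 39 piglets only. It was not adjusted over the many split tests, so it is weak evidence. Without batch 2 edgeR called 0 genes and with surrogate variables 1, where the splits say nothing. The highest others gave 278, 118 and 32 genes, all above the real 12, and the cause was not tested. These 3 splits kept 7, 6 and 8 of the 9 severe piglets in the severe group, and the 4 severe piglets of batch 2, which has no mild one, stayed there in every split.

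Chance can be excluded for the 13 genes of male against female piglets (1 of 100 splits, highest other 11). At an unadjusted p under 0.05, 2 of 100 splits reached the 1549 genes of NEC against CON (highest other 2749). For the 1995 genes of severe against CON it was 3 of 100 (highest other 2153). These tests were chosen after the values were seen and not adjusted over the many split tests, so they do not exclude chance. Nor is chance excluded for the 841 genes of mild against CON (12 of 100, highest other 1810) or the 1355 of severe against mild (6 of 100, highest other 2194). A count of 0 in edgeR is reached by all 100 splits whatever the data, so these splits say nothing of chance there; the highest other was 1 for NEC against CON, 8 for mild against CON, 5 in batch 1 and 2 in batch 2. Chance cannot be excluded for the number of gene lists that camera called with its preset correlation. For NEC against CON the 5 lists were reached by 89 of 100 splits (highest other 21), for mild against CON the 6 lists by 79 (highest other 21), for severe against CON the 15 lists by 14 (highest other 19) and for severe against mild the 19 lists by 9 (highest other 22).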

How the results depend on the processing

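The settings without 3 doubted libraries (CON replicate 16, NEC_Severe replicates 2 and 9) and without the 2 most abundant genes were chosen after seeing the data, as were NEC against CON without batch 2 and the composition of mild and severe libraries apart, with and without the BKDL controls. The cause was not tested for any change below, except that settings which leave out piglets test fewer samples.

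With DESeq2 the genes called were 55 for NEC, 20 for mild and 542 for severe against CON, 103 for severe against mild, 4 and 9 for the interactions of NEC with batch and sex, and 93 for sex. With limma they were 127 for NEC and 1701 for severe against CON, and 818 for severe against mild. For severe against CON edgeR called 127 without a low-count filter, 38 without batch and sex terms, 92 with the title number in place of batch and 70 without the BKDL controls (68 of them among the 224); without batch 2 it called 12, of which 4 were among the 224. With 8 surrogate variables it called 0 (818 at an unadjusted p under 0.05), with 222 of 224 signs kept at 42.5% of the median size. For severe against mild the count was 1 with surrogate variables, 33 without the BKDL controls, 19 without the doubted libraries and 0 without batch 2 (1474 at an unadjusted p under 0.05). Without batch 2 it was 5 for NEC and 2 for mild against CON. Batch 3 had 0 calls fitted alone and 0 without the BKDL controls (715 and 387 at an unadjusted p under 0.05). Every other setting tried kept these counts within 1.5 times; for severe against CON they were 217 to 263, with 118 of the 224 among the 217 called without the doubted libraries.

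Leaving out each piglet in turn gave 0 to 1 genes for NEC (1 without NEC_Mild replicate 11) and 0 to 0 for mild against CON. For severe against CON it gave 12 to 721: beyond 1.5 times lay CON replicates 2 (130), 11 (133) and 18 (139) and NEC_Severe replicates 1 (55), 2 (12), 4 (79), 5 (91), 6 (105), 8 (103) and 9 (721). For severe against mild it gave 5 to 104: NEC_Mild replicates 1 (6), 7 (104) and 9 (28), NEC_Severe replicates 1 (6), 3 (32), 7 (32), 8 (5) and 9 (56), and CON replicates 10 (40) and 19 (19).

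Gene lists called with an estimated correlation numbered 0, 0, 0 and 1 for NEC, mild and severe against CON and severe against mild, and with fry 0, 0, 4 and 4; without the BKDL controls 10 were called for mild. The difference in counts on genes was 2.01 M without them. Reversed values were the score in batch 2 with 20 and 20 genes (-0.18), and, without the BKDL controls, the mild difference in globin share (-1.97 points) and in the share of the 10 most abundant genes (-2.67 points). FKBP5 reversed in NEC with surrogate variables (-0.10). In mild piglets FKBP5 read -0.0925 with limma, -0.0008132 without a low-count filter, -0.0187 without batch and sex terms, -0.28 with surrogate variables, -0.13 without the BKDL controls, -0.0260 without the doubted libraries, and -0.0846 to 0.089 with single piglets left out. ARG2 read -0.24 between the grades with surrogate variables. Of the named genes' values with 1 piglet left out, 1350 kept sign and side of the threshold, 109 lost their call, 4 gained one and 19 changed sign; under the other settings these were 427, 79, 17 and 8. Of the 14 named genes called in severe piglets, ID3 kept its call without any single piglet, while NEC_Severe replicate 2 ended 13 calls and replicate 1 ended 10. Depth limits genes near the filter: 1.51 to 12.6 M counts per library lay outside the 2 most abundant genes.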

Other observations

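Metabolic and oxidative genes gave single calls in severe piglets against CON. PFKFB2, which makes the activator of phosphofructokinase, rose by log2 1.55 ± 0.34 (edgeR FDR 0.0167), while P4HA1 read 0.59 ± 0.21 and LDHA 0.53 ± 0.21, and 19 of 33 hypoxia and glycolysis genes read above CON (camera adjusted p = 0.161). NFE2L2, a transcription factor of the antioxidant response, rose by 0.59 ± 0.16 (FDR 0.0423), with the superoxide dismutase SOD2 at 1.07 ± 0.34 not passing; 17 of 26 oxidative burst genes read higher (camera adjusted p = 0.0603). MS4A2, the beta chain of the mast cell and basophil IgE receptor, rose by 0.76 ± 0.19 (FDR 0.0253), though 6 of 11 genes of its list read lower. Of 22 arginine and polyamine genes 9 read higher and none passed, with AZIN1 at 0.83 ± 0.27 and the amino acid transporter SLC7A7 at 0.92 ± 0.31.

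Other lists gave no call against CON in severe piglets. Natural killer and cytotoxic genes read higher in 13 of 20, NKG7 at 0.74 ± 0.29, and MHC class I genes lower in 10 of 15, ERAP2 at -0.49 ± 0.18 (camera adjusted p = 0.808 and 0.0603). Cell cycle genes read lower in 22 of 40 (adjusted p = 0.656) and stress genes of the endoplasmic reticulum and heat shock higher in 15 of 28, ATF6 at 0.59 ± 0.21 (adjusted p = 0.161). RSAD2, an interferon-induced gene, read -1.15 ± 0.49. Dendritic cell genes were lower in 8 of 12 for severe against mild (camera adjusted p = 0.0404; adjusted p = 0.162 with an estimated correlation). Of the gut and liver epithelium list CDH1 alone was tested, at 0.62 ± 0.30 in severe piglets. The mean of the B cell list was lower in severe than in CON piglets in each batch, at 0.88 against 1.46 in batch 2.

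Median, mean and test of a list differed in sign for some lists, none of them called. These were the hypoxia, oxidative phosphorylation and cell cycle lists for NEC against CON, and the eosinophil, cytokine, inflammasome, MHC class I and oxidative phosphorylation lists for mild. They were the eosinophil, arginine, oxidative phosphorylation and cell cycle lists for severe against CON, and the natural killer, eosinophil and arginine lists for severe against mild.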
